A study of Microcystis aeruginosa PCC 7806 with 2 samples.

How the data were processed

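Total RNA of the toxin-forming cyanobacterium Microcystis aeruginosa PCC7806 was sequenced in 2 libraries. The control library came from an untreated culture, and the H2O2 library from a culture given 140 µM hydrogen peroxide. The series' design text gives an exposure of 1 h at 25 °C in light. Per the labels, cells were in mid-exponential growth, RNA was taken with an RNeasy kit, and libraries were made with a TruSeq kit that keeps strand. The growth label of both samples mentions treated medium, and the control was assigned from its agent label, which reads none. Nothing in the labels says how many cultures stand behind a library.

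The deposited table lists genes by locus tag or symbol with a product text, an eggNOG category and values for both libraries. Bowtie2 is named in the submitters' processing notes, with no version. The counting tool and the genome build are not given in the sources used here, and the table gives gene order on 1 contig but no coordinates. The read columns were deposited as whole numbers and were treated as estimated counts. This reading rests on 29 control and 49 H2O2 rows with 0 reads but a normalized value above 0. The other per-library columns carry no unit in the header, and their values behave as RPKM computed by the authors from the same reads. The authors' deposited table also holds a DESeq2 p-value and an edgeR p-value per gene, and its headers do not say whether they were adjusted. No other columns of per-sample values were present.

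The table has 5419 rows. Of these, 149 rows with more than 5 control reads share all values with another row, among them genes listed at both ends of the contig. Such rows can be 1 gene listed again or copies that share reads, and the table does not tell which. How the authors assigned reads that match several genes is not given in the sources used here, so values of single copies of a repeated gene are uncertain. The product text of 13 rows was withheld, and these genes are not reported here. No reference genome was used.

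Effective library sizes were the total reads multiplied by TMM factors from edgeR 4.0.16 in R 4.3.3, which were 0.952 for the control and 1.05 for the H2O2 library. The log2 ratio of H2O2 over control was taken after adding 0.5 to each count. Genes with at least 20 reads in the higher library were kept, which left 2673. Each fold carries an exact 95% conditional-binomial interval, computed without the added 0.5. Where a library had 0 reads, the fold is a bound against a floor of 3 counts in that library, which takes the other count as exact and is less strict than the interval, equal to 4.36 CPM in the control and 14.9 in the H2O2 library. Intervals and floors cover counting error only, since 1 library per group leaves differences between cultures and preparations unmeasured. The reads carry no molecular identifiers, so copies of 1 molecule could not be set apart and the intervals may be too narrow.

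With 1 library per group no test across conditions was possible, no p-value was computed, and no difference has a replicate check. Genes were counted by size, at 2-fold. A total of 30 gene lists were defined by patterns on symbols and product texts. Each list is described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 10 bins. Random lists drew genes without regard to position, so the percentiles do not allow for like ratios of adjacent genes. The genes named were the 12 annotated genes furthest in each direction among those with at least 100 reads in the higher library and at least 2-fold apart. To these were added up to 4 members per list with the largest absolute log2 ratio at that depth, all microcystin synthetase genes, the 5 most abundant annotated genes per library and 2 unannotated genes each way. A product text counted as annotation when it held more than a cross-reference or a general keyword. The scaling, the filters, the lists, the naming rule and the first set of alternatives were fixed before the data were examined.

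Alternatives were total counts, DESeq2 1.42.0 size factors, totals without the 20 most abundant genes, and the deposited RPKM on the log2(value + 1) scale. These were set first, together with no minimum count, a minimum of 100, a pseudocount of 5, thresholds of 1.5-fold and 4-fold, intervals beyond 2-fold, and removal of product names found in more than 3 genes. For lists, members by symbol only and the mean in place of the median were tried. After the data were seen, a pseudocount scaled to library size, a length correction, single counting of identical rows and lists without 61 members of another function were added. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated counts of this comparison with 100 genes set 4-fold higher and 100 set 4-fold lower. The changed genes were drawn only from those with at least 20 reads expected in the H2O2 library before the change. Of these, 100% of the raised and 98% of the lowered genes came out at least 2-fold apart. Recovery of kept genes with fewer H2O2 reads was not tested. Among 2730 simulated genes past the filter, 4.07% of those with no set change also came out at least 2-fold apart. The intervals held the true ratio in 96.6% of genes. The simulated counts were Poisson draws, which is the error the intervals assume, so this checks the computation only. Variation between cultures or preparations was not simulated.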

Results

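The series asked how the transcriptome of Microcystis aeruginosa PCC7806, a bloom-forming cyanobacterium that makes the hepatotoxin microcystin, differs after 1 h with 140 µM hydrogen peroxide. One control library (n = 1) and 1 H2O2 library (n = 1) were sequenced. The control held 722050 reads over the listed genes and the H2O2 library 191136, a 3.78-fold gap in depth. Reads were found for 4214 genes in the control and 3851 in the H2O2 library, and at least 20 reads for 2642 and 1462 genes. The 10 most abundant genes took 18.4% of control reads (Wilson 95% interval 18.3% to 18.5%) and 20.6% of H2O2 reads (20.4% to 20.7%). All 48 ribosomal and transfer RNA rows had 0 reads in both libraries, so they show nothing of RNA quality. The annotated genes with most control reads were psaA with 26538, the D1 gene BH695_4579 with 16128, psaB with 15771, cpcA with 12142 and cpcB with 11896. In the H2O2 library BH695_4579 had 6149 reads, the D1 gene BH695_4385 5511, psaA 5118, the D1 gene BH695_4597 4019 and psaB 3901.

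Several heat-shock and iron-transport genes, the sigma factor genes rpoD and BH695_3943, and the summed reads of the D1 genes were higher in the H2O2 library. The microcystin synthetase genes, both glutamine synthetase genes, and many phycobilisome and chlorophyll synthesis genes were lower. The small heat-shock gene hspA was 42.7-fold higher (95% counting interval 33.5 to 55.3), with 70 control and 873 H2O2 reads. The glutamine synthetase gene glnA, which encodes the enzyme that joins ammonium to glutamate, was 49.7-fold lower (26.1 to 109), with 1532 and 9 reads. All 10 microcystin synthetase genes were at least 2-fold lower. Of 2673 genes, 328 were at least 2-fold higher and 613 at least 2-fold lower. The lower genes made up 65.1% of these, against 54.9% when libraries were scaled by totals without the 20 most abundant genes. That scaling moved the median log2 ratio of all kept genes from -0.20 to -0.02. The excess of lower genes also depended on the filter and the pseudocount. With no minimum count 898 genes were higher and 882 lower, and with at least 100 reads 105 and 354. An unscaled pseudocount of 5 gave 381 and 371, but 5 scaled to library size gave 277 and 553. The counting interval lay wholly beyond 2-fold for 150 higher and 243 lower genes. With 1 library per group, none of these differences has a replicate check. In the authors' deposited table, the DESeq2 column was below 0.05 for 85 genes, of which 50 had a higher and 35 a lower log2 ratio here. The edgeR column of the authors' deposited table was below 0.05 for 185 genes, 71 higher and the others lower.

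**Figure D1:**
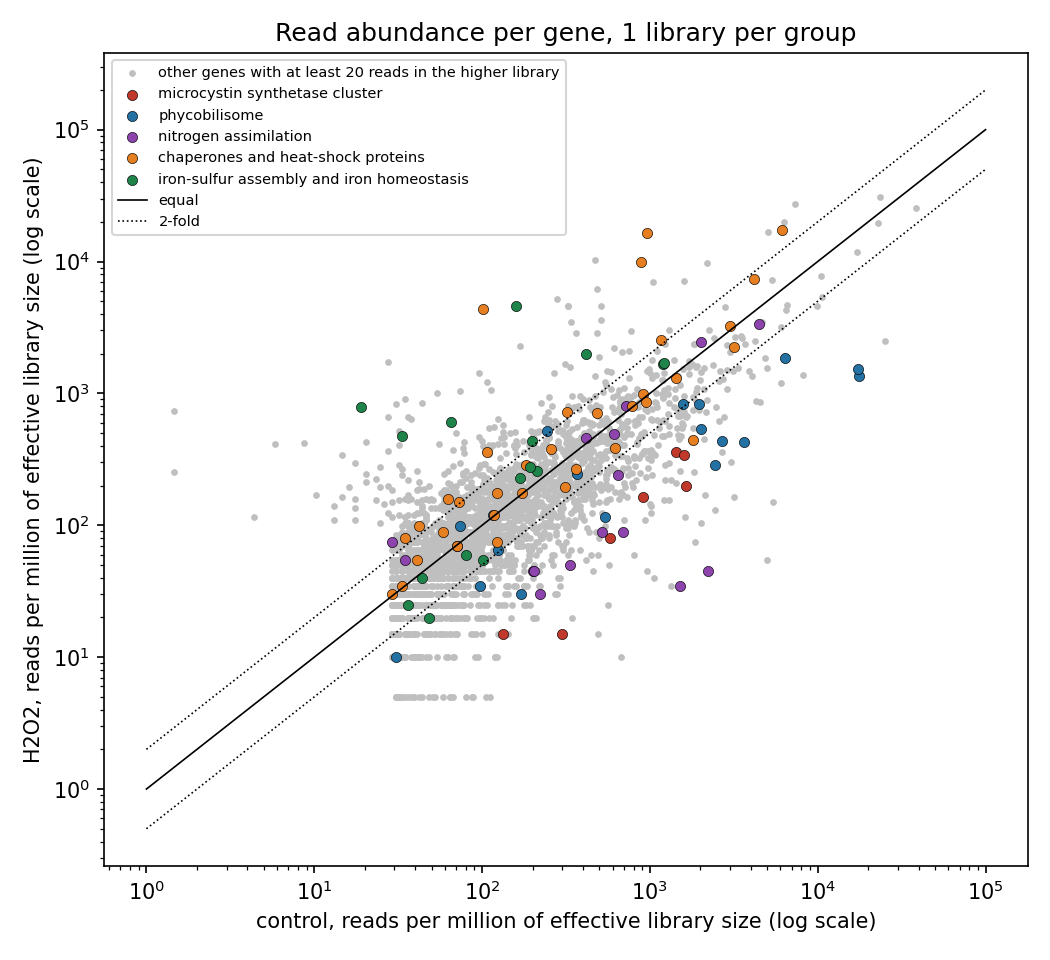
CPM (reads scaled to effective library size) in the control (x axis, log scale) and the H2O2 library (y axis, log scale), 1 point per gene with at least 20 reads in the higher library; genes with 0 reads in either library are not drawn. The microcystin synthetase genes shown lie below the lower 2-fold line, and hspA stands at 42.7-fold above equality among the chaperone genes.

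Among annotated genes with at least 100 reads in the higher library, the largest ratio belonged to BH695_3611, a DNA-binding regulator by its keywords, at 62.5-fold higher (39.4 to 105) from 19 and 347 reads. At that depth it was followed by hspA and by the iron-transport genes BH695_3621, 41.6-fold higher (23.6 to 79.9), and BH695_3620, 29.1-fold higher (23.8 to 35.8). The metallopeptidase gene BH695_4591 was 21.7-fold higher (19.3 to 24.5) and the peptidase gene BH695_3568 19.4-fold (13.1 to 29.6). BH695_5117, annotated as a hydrogenase subunit, was 18.7-fold higher (13.1 to 27.3), and the chaperone gene BH695_0938 17.1-fold (15.7 to 18.6). The aminotransferase gene BH695_2555 was 16.9-fold higher (11.0 to 26.8), and the glycine oxidase gene BH695_1063 14-fold (10.2 to 19.4). BH695_3587, with chlorophyll and stress-response keywords, was 14.9-fold higher (11.4 to 19.8). The sigma factor gene rpoD, listed in a pair of identical rows, was 14.1-fold higher (12.2 to 16.4). Of unannotated genes at that depth, BH695_1296 went from 1 to 147 reads, 503-fold higher with a wide interval (88.9 to 20010), and BH695_0968 was 27.2-fold higher (17.2 to 45.2).

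At the other end, 4 annotated genes with at least 100 control reads had 0 reads in the H2O2 library. These were 1 hypB row, a nickel-insertion gene for hydrogenase, at least 12.8-fold lower, and mcyF, at least 12.3-fold lower. The others were BH695_2341, with endonuclease and transposition keywords, at least 12.2-fold lower, and BH695_4051, annotated as an oxaloacetate-decarboxylating malate dehydrogenase, at least 10.4-fold lower. The other hypB row was 2.55-fold higher (1.56 to 4.12), from 43 and 32 reads. The agmatinase gene speB2 was 67.2-fold lower (18.5 to 556), with 2 reads left. Next came glnA and a second glutamine synthetase gene, BH695_4660, at 43.3-fold lower (20.9 to 108). The unannotated genes BH695_2482 and BH695_2484 were 90.8-fold lower (50.7 to 182) and 36.2-fold lower (25.3 to 53.8).

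Microcystin is built by a modular peptide and polyketide synthetase encoded by the mcy genes. Their median log2 ratio was -2.98, below all 10000 matched random lists (percentile 0), and -2.67 with the 3 genes at 0 H2O2 reads set at their bound. The mcy genes are adjacent in gene order while random lists draw genes from anywhere, so the percentile may overstate how unusual the set is. Summed over the cluster, 4741 control and 236 H2O2 reads gave a ratio 5.87-fold lower (5.15 to 6.71). The peptide synthetase genes mcyA, mcyB and mcyC were 4.61-fold (3.62 to 5.97), 5.51-fold (3.89 to 8.08) and 20.1-fold lower (6.77 to 98.0). The polyketide synthase gene mcyD was 4.0-fold lower (3.15 to 5.15). The polyketide and peptide synthetase fusion gene mcyE was 8.28-fold lower (6.04 to 11.7). For mcyG, annotated with a peptide synthetase domain, the ratio was 7.21-fold lower (4.39 to 12.7). The methyltransferase gene mcyJ was 8.86-fold lower (2.94 to 43.8). The racemase gene mcyF, mcyI and the transporter gene mcyH had 0 H2O2 reads, against 126, 59 and 31 in the control, which made them at least 12.3-fold, 5.74-fold and 3.02-fold lower against the floor of 3 counts. The exact 95% interval, which also carries the error of the control count, starts lower, at 9.83-fold, 4.53-fold and 2.31-fold. The list of other secondary-metabolite genes held mcyD, mcyE, mcyG and the halogenase gene aerJ, and all 4 were lower (median -2.50, percentile 0.34). Only aerJ, 4.72-fold lower (2.70 to 9.01), is not a microcystin gene.

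**Figure D2:**
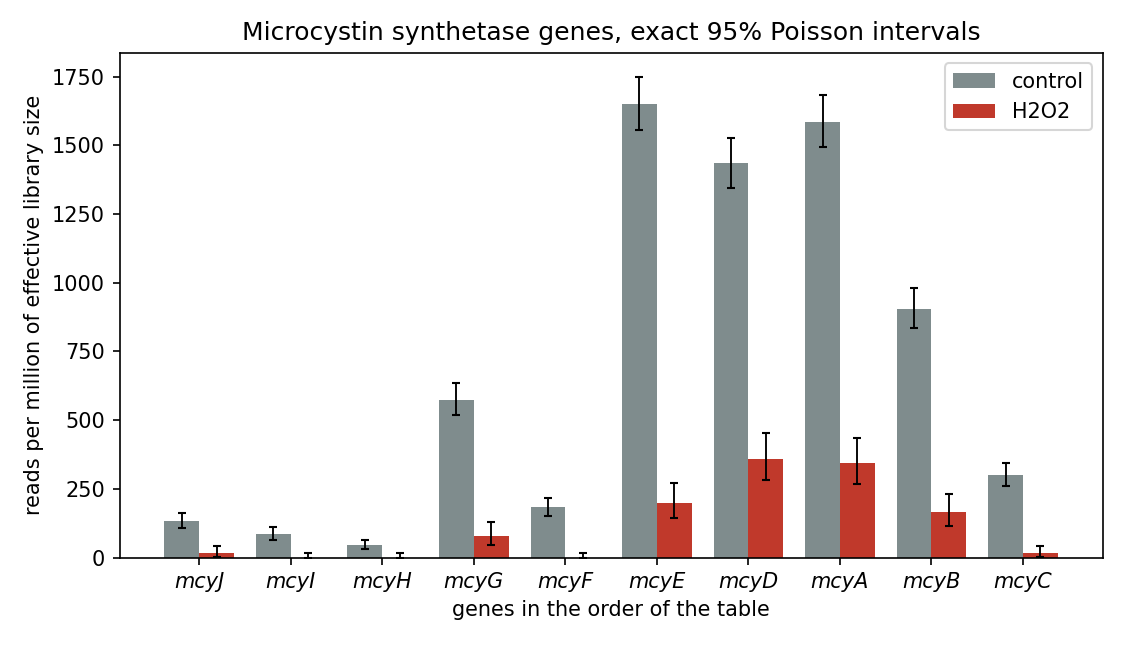
CPM (reads scaled to effective library size, y axis) for the 10 microcystin synthetase genes in table order, control and H2O2 side by side, with exact 95% Poisson intervals for counting error. All 10 bars are lower in the H2O2 library, and mcyI, mcyH and mcyF stand at 0 there.

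Nitrogen assimilation genes had a median log2 ratio of -1.42 (percentile 0.03), with 9 of 17 measured members at least 2-fold lower and 1 higher. That median was -0.36 with no minimum count and -0.41 without members of another function, so it depends on which members enter. Beside both glutamine synthetase genes, the more abundant nrtC row of the nitrate transporter was 7.68-fold lower (4.80 to 13.1) and the nitrate reductase gene narB was 7.40-fold lower (3.32 to 20.5). The other nrtC row, from only 20 and 15 reads, was 2.57-fold higher (1.22 to 5.28). It is the 1 higher member counted above and is also listed under carbon fixation, so whether it belongs to the nitrate transporter is uncertain.

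Light-harvesting and electron-transport genes were mostly lower. Of 18 phycobilisome genes, which encode the antenna that feeds the photosystems, 12 were at least 2-fold lower and 1 higher (median -1.59, percentile 0.02). The phycocyanin genes cpcA and cpcB were 13.0-fold (11.6 to 14.8) and 11.3-fold lower (10.1 to 12.7), and cpcI and apcA 8.50-fold each. Chlorophyll, heme and bilin synthesis had 16 of 29 genes lower and 1 higher (median -1.28, percentile 0). The heme oxygenase gene hO1 was 26.7-fold lower (13.5 to 62.1), chlP 24.7-fold (14.9 to 44.2), the cyclase gene BH695_3565 18.9-fold (12.9 to 29.0) and chlB 14.1-fold (9.35 to 22.4). In photosystem I, 6 of 11 genes were lower and 1 higher (median -1.09, percentile 2.48). The genes psaK2, psaD and psaL were 5.26-fold, 4.65-fold and 4.32-fold lower, and the higher member was the stress-keyword gene BH695_3587. The far more abundant psaA and psaB were 1.51-fold (1.47 to 1.56) and 1.18-fold lower (1.14 to 1.22). ATP synthase had 9 of 12 genes lower and 0 higher (median -1.58, percentile 0.03), with atpH 5.09-fold lower (2.40 to 12.9) and 1 atpC row 4.18-fold (2.79 to 6.55). In the NDH-1 complex 11 of 21 genes were lower and 0 higher (median -1.06, percentile 0.89), and BH695_2781 was 3.51-fold lower (1.95 to 6.94). The 5 cytochrome b6f and related genes had a median of -1.15 (percentile 8.66), with petC 2.86-fold lower (2.17 to 3.82) and petA 2.84-fold (2.33 to 3.49).

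Photosystem II was mixed, with 3 of 13 genes at least 2-fold higher and 3 lower (median -0.74, percentile 16). The higher members were the D1 genes BH695_4385 and BH695_4597 and 1 psbD row. All measured members other than the D1 and D2 genes had log2 ratios below 0, from -0.424 for psbC to -1.525 for psbH. The D1 protein, the reaction-centre subunit replaced most often under light stress, is annotated for 3 genes with the same product text. BH695_4385 was 3.76-fold higher (3.62 to 3.91), BH695_4597 3.17-fold (3.04 to 3.31) and BH695_4579 1.31-fold (1.27 to 1.34). How reads were assigned among them is unknown, and their sum was 2.11-fold higher (2.07 to 2.15) from 25485 and 15679 reads. The 2 psbD rows, for the D2 protein, summed to 1.83-fold higher (1.76 to 1.90), with 1 row at a log2 ratio of 1.73 and the other at -0.59. The assembly gene psbW was 2.77-fold lower (1.97 to 4.0).

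Carbon fixation and carboxysome genes had 7 of 12 lower and 2 higher (median -1.17, percentile 0.73). Rubisco's large-subunit gene rbcL was 4.87-fold lower (4.19 to 5.70), its chaperonin gene rbcX 4.06-fold (3.27 to 5.09), the shell gene ccmK 3.61-fold (2.40 to 5.67) and rpe 7.16-fold (3.56 to 16.8). Glycogen and central carbon had 10 of 31 lower and 1 higher (median -0.52, percentile 16), with the transketolase gene BH695_0372 7.24-fold lower (5.48 to 9.78) and glpX 4.17-fold (3.50 to 5.01). Ribosomal protein genes had 22 of 42 lower and 2 higher (median -1.03, percentile 0). There rplB was 9.05-fold lower (4.08 to 25.0) and rplW 7.45-fold (2.82 to 27.9). Translation factors and tRNA synthetases had 14 of 33 lower and 0 higher (median -0.84, percentile 0.23), with the elongation factor gene BH695_1112 5.91-fold lower (3.40 to 11.2) and valS 4.56-fold (2.41 to 9.69).

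Chaperone and heat-shock genes, many of whose products refold damaged proteins, stood at the other side. Of 34 measured, 11 were at least 2-fold higher and 1, rbcX, lower (median 0.50, percentile 99.95). The higher members include 1 hypB row, a hydrogenase gene. The other 22 lay within 2-fold, among them dnaK1 at a log2 ratio of 0.021, groL1 at 0.812, clpB1 at -0.659 and grpE at -0.688. After hspA and BH695_0938 came the ATP-binding chaperone gene BH695_3337, 11.2-fold higher (10.3 to 12.3). Iron-sulfur and iron homeostasis genes had 6 of 16 higher and 1 lower (median 0.48, percentile 99.5). After BH695_3621 and BH695_3620, the iron-transport genes BH695_4319 and BH695_0119 were 9.28-fold (6.55 to 13.4) and 4.79-fold higher (4.11 to 5.60). Among 17 RNA polymerase and sigma factor genes 4 were higher, 2 of them the identical rpoD rows, and 4 were lower (median -0.24, percentile 65.6). The sigma factor gene BH695_3943 was 5.38-fold higher (4.52 to 6.42) and nusG 3.78-fold (3.02 to 4.73), while the sigma factor gene BH695_2386 was 4.36-fold lower (2.54 to 8.11). A separate row, rpoD1, with 812 control and 198 H2O2 reads, had a log2 ratio of -0.258. Energy-dependent proteases had 2 of 15 higher and 1 lower (median -0.09, percentile 65.4), with ftsH3, a membrane protease gene, 4.49-fold higher (4.2 to 4.8).

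Peroxide-removing genes differed in both directions. Of 10, 2 were at least 2-fold higher and 2 lower (median -0.13, percentile 55.4). The peroxiredoxin gene BH695_0161 was 6.73-fold higher (6.14 to 7.37) and BH695_0509 1.75-fold (1.54 to 1.99), whereas the peroxiredoxin gene BH695_2635 was 2.46-fold lower (2.11 to 2.89) and the superoxide dismutase gene sodB 1.59-fold (1.09 to 2.39). In the thioredoxin and glutathione list 2 of 11 were higher and 2 lower (median -0.01, percentile 68.2). The thioredoxin reductase gene BH695_5085 was 5.96-fold higher (5.20 to 6.85) and gshB 2.0-fold (1.48 to 2.70), and the glutamate-cysteine ligase gene BH695_4049 was 6.85-fold lower (5.03 to 9.57). Photoprotection genes had 0 of 9 higher and 1 lower (median -0.43, percentile 25.0), with the beta-carotene hydroxylase gene BH695_0570 2.26-fold lower (1.74 to 2.97). DNA repair genes had 3 of 30 higher and 1 lower (median 0.27, percentile 96.3). The helicase gene BH695_4838 was 2.62-fold higher (1.94 to 3.53), the ERCC-like gene BH695_3413 2.43-fold lower (1.72 to 3.54) and the lexA-annotated repressor gene BH695_2602 2.03-fold lower (1.32 to 3.26). The last is not among the genes counted as lower, since the 0.5 added to each count for the log2 ratio brings it just under 2-fold. With fewer than 100 reads and outside the naming rule, the repair gene recO had the largest ratio of the list, 47.9-fold higher (21.1 to 134), and was named after its value was seen.

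**Figure D3:**
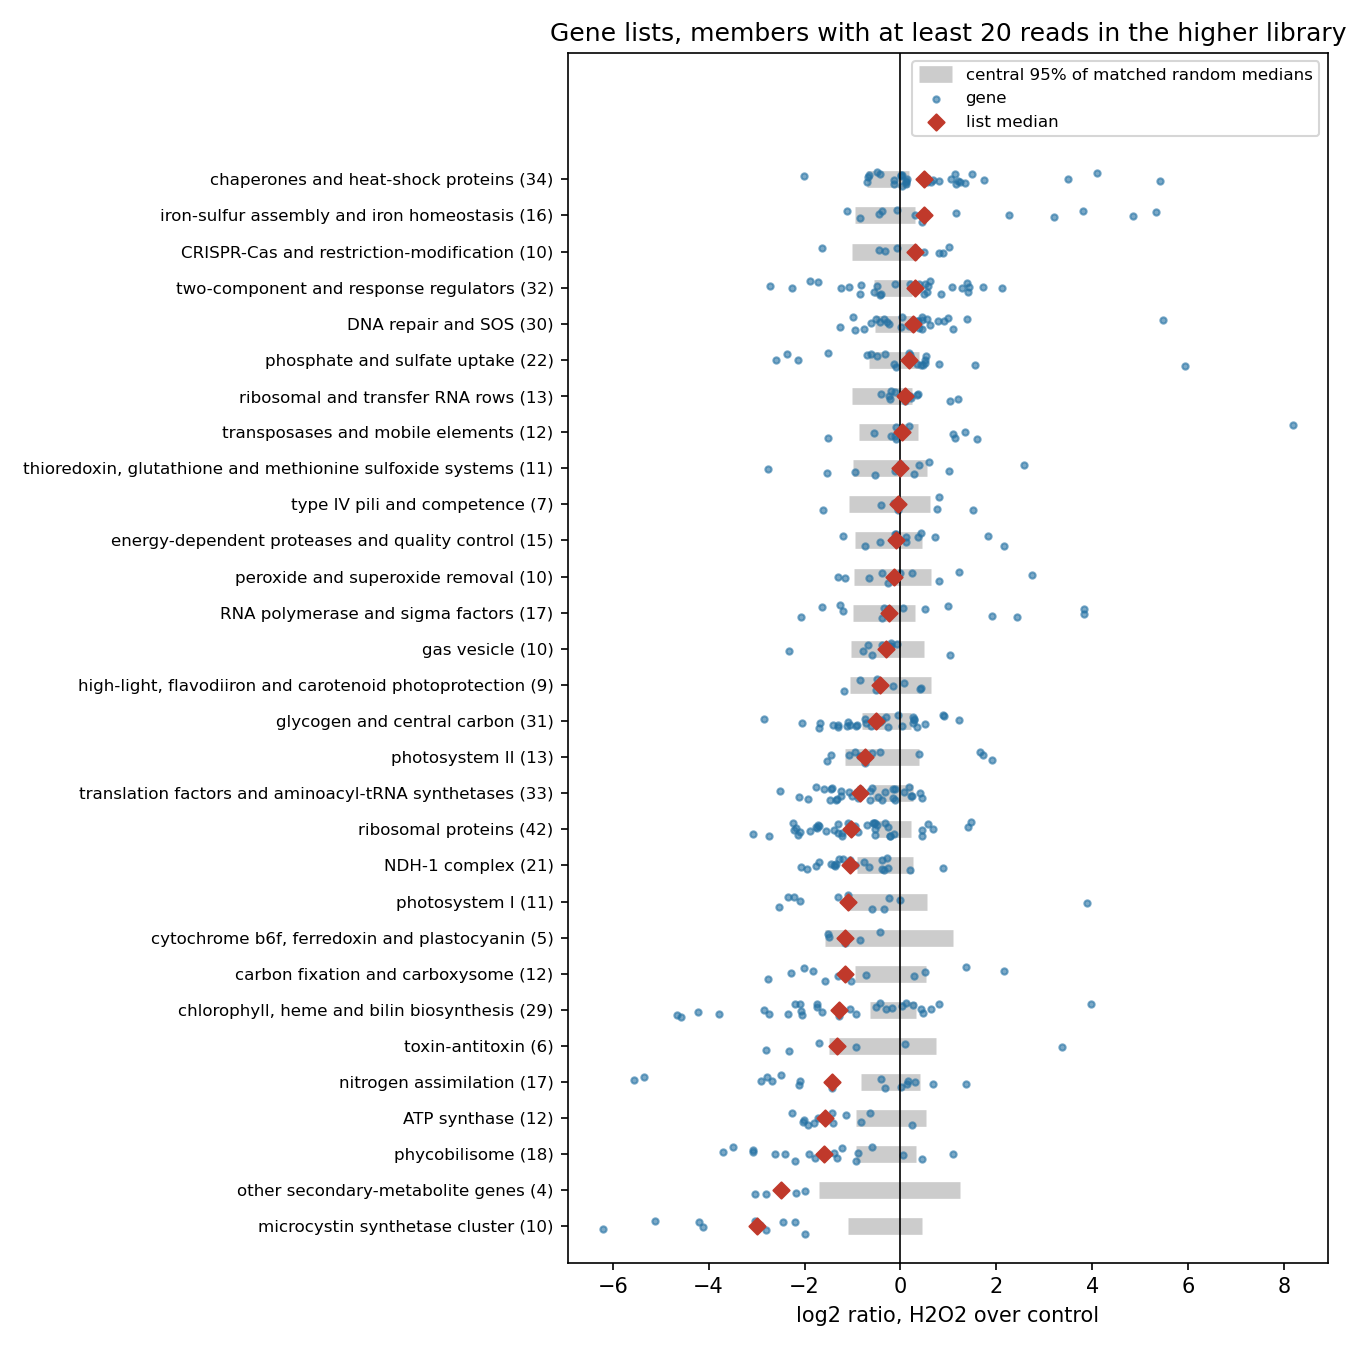
Log2 ratio of H2O2 over control (x axis) for the measured genes of each list (rows, number of genes in brackets), with list medians as diamonds and grey bands for the central 95% of medians of matched random lists. The microcystin median of -2.98 lies left of its band, and the chaperone median of 0.50 and the iron median of 0.48 lie right of theirs.

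The remaining lists held smaller or mixed differences. Two-component regulators had 7 of 32 higher and 6 lower (median 0.30, percentile 98.8), with the manganese-sensing kinase gene BH695_4943 4.32-fold higher (3.26 to 5.74) and the kinase gene BH695_4033 7.19-fold lower (3.0 to 22.5). Phosphate and sulfate uptake had 2 of 22 higher and 4 lower (median 0.18, percentile 87.6). Apart from BH695_3611, the sulfate-assimilation genes cysC and sat were 6.11-fold (4.52 to 8.47) and 5.29-fold lower (3.29 to 9.04). Gas vesicle genes, whose products give buoyancy, had 1 of 10 higher and 1 lower (median -0.30, percentile 43.4), and gvpC was 1.52-fold lower (1.29 to 1.80). Type IV pilus and competence genes had 1 of 7 higher and 1 lower (median -0.06, percentile 60.7; 0.76 without members of another function). Transposases had 5 of 12 higher and 1 lower (median 0.04, percentile 81.6), and many of their rows share a symbol. CRISPR and restriction genes had 1 of 10 higher and 1 lower (median 0.31, percentile 96.6; -0.32 by symbol only), and the cas3 gene BH695_4158 was 1.40-fold higher (0.982 to 1.98). The toxin-antitoxin pattern had 1 of 6 higher and 3 lower (median -1.32, percentile 4.51), but its median was 0.60 with no minimum count and 0.09 without members of another function. Its 4 largest ratios were of other genes, namely mcyG, the 3-phytase gene BH695_0980, the adenylate cyclase gene BH695_2244, 10.3-fold higher (8.91 to 12.1), and the endoglucanase gene BH695_1183, 5.03-fold lower (4.41 to 5.75). The ribosomal and transfer RNA pattern measured 13 genes for RNA-modifying and related proteins, of which 2 were higher and 0 lower (median 0.10, percentile 92.3), among them the pseudouridine synthase gene BH695_2011, 2.28-fold higher (1.80 to 2.88).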

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

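Pseudocount scaling, length correction, single counting of identical rows and list pruning were chosen after the data were seen. The 328 higher and 613 lower genes became 573 and 930 at 1.5-fold, 101 and 203 at 4-fold, 150 and 243 with intervals beyond 2-fold, and 105 and 354 with at least 100 reads, by the construction of those settings. With no minimum count 898 were higher and 882 lower. A pseudocount of 5 gave 381 higher and 371 lower genes, since the same number weighs more in the shallower library, and 5 scaled to library size gave 277 and 553. Total counts gave 406 and 533, DESeq2 size factors 348 and 592, the deposited RPKM 387 and 569, and totals without the 20 most abundant genes 418 and 509. Length correction, which sets the median of each length decile to 0, gave 408 and 500. No list outside the central 95% of its random medians changed sign. The microcystin median was -2.19 with a pseudocount of 5. The DNA repair median was 0.45 without the 20 most abundant genes in the totals, a scaling that shifts every log2 ratio by the same amount. It was 0.48 after length correction, which recentres each decile, and -0.36 with at least 100 reads, where fewer members enter. The median of the ribosomal and transfer RNA pattern was 0.64 with at least 100 reads, where only BH695_2011 and BH695_1515 are left. With a pseudocount of 5, which weighs more in the shallower library, it was 0.45. The other list medians stayed within their binomial interval wherever a setting gave a value, but for short or mixed lists that interval is wide and the shift exceeded 1.5-fold in the cases that follow. The nitrogen median of -1.42 was -0.36 with no minimum count, -2.10 with at least 100 reads and -0.41 without members of another function, and the toxin-antitoxin median of -1.32 was 0.60 with no minimum count and 0.09 without such members, with a mean of -0.72. The iron mean was 1.25 beside a median of 0.48, and the transposase mean 0.92 beside 0.04. The transposase mean includes a uma4 row at a log2 ratio of 8.185, from 0 control and 42 H2O2 reads. It is the only kept gene with 0 control reads. The type IV pilus median of -0.06 was 0.76 without members of another function. By symbol only, the CRISPR and restriction median of 0.31 was -0.32, thioredoxin and glutathione 0.80, phycobilisome -2.31 and chlorophyll synthesis -2.09. With at least 100 reads, phycobilisome was -2.21, chlorophyll synthesis -1.90 and carbon fixation -1.83. Beyond the uma4 row, the cause of these shifts was not tested. By construction, 5 lists had no members by symbol only and 2 none with at least 100 reads. The direction of the 129 named rows past the filter held under total counts, DESeq2 size factors, the totals without abundant genes and the deposited RPKM. Apart from RPKM, these settings add the same amount to every log2 ratio, moving the median of kept genes from -0.20 to at most -0.02. Named rows were mostly picked for large ratios, so their signs could hardly change and this says little about robustness. Leaving out ribosomal and transfer RNA rows removed 0 reads. Depth limits the lower side: 25 kept genes had 0 H2O2 reads. No paired analysis was possible because each group has 1 library.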

Other observations

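Adjacent genes tended to have like ratios. Across genes, log2 ratios of 1550 pairs of adjacent kept rows had a Spearman correlation of 0.446. The highest of 1000 shuffles reached 0.0776. Genes are not independent replicates, and the percentiles of gene lists do not allow for this. A total of 24 stretches of 4 or more adjacent genes were all at least 2-fold lower, against at most 7 in a shuffle, and 9 were all higher, against at most 2. These stretches were chosen after their values were seen. The 6 genes from BH695_2477 to BH695_2482 summed to 7429 control and 111 H2O2 reads, 19.6-fold lower (95% counting interval 16.2 to 23.8). The 6 genes from BH695_5178 to BH695_5183 were 7.16-fold lower (6.14 to 8.39), and the 13 ribosomal protein genes from rplE to rplC 3.76-fold (3.20 to 4.45). The lower stretch that holds the microcystin genes has 11 members and ends with uma1. Among higher stretches, the 4 genes from BH695_3611 to BH695_3614 were 22.8-fold higher (17.9 to 29.4), and rplA and rplK, with nusG, lay in one that was 3.07-fold higher (2.77 to 3.42), opposite to most ribosomal protein genes. The flavodoxin gene isiB, also named after its value was seen, was 14.1-fold higher (8.89 to 23.4).

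By eggNOG category, added after the data were seen, category J (translation) had 47 of 134 genes at least 2-fold lower and 5 higher, with a median log2 ratio of -0.60 (percentile 0). Category M (cell envelope) had 37 of 143 lower and 6 higher (median -0.53, percentile 0.02). Category S (function unknown) had 134 of 918 higher and 164 lower, and its median of -0.06 lay above its random lists (percentile 100). Category T (signal transduction) had 17 of 78 higher and 11 lower (median 0.22, percentile 99.9).

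In the tests that follow, those of summed reads and of scaling were chosen after the result was seen. The microcystin genes were lower as a set. Counting error is argued against by the upper bound of the summed H2O2 to control ratio, 0.194, below 0.5. So is a loss with gene length: among random lists matched on effective length the cluster median had percentile 0. A lower transcript level after H2O2 may account for the pattern as a hypothesis, and a difference between the 2 cultures or preparations stays open with 1 library per group.

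Reads summed over the D1 genes and over the psbD rows for D2 were higher. The other measured photosystem II genes had log2 ratios below 0. Summed phycobilisome reads were 6.15-fold lower (5.88 to 6.45), with 12 of 18 genes at least 2-fold lower. In photosystem I, 6 of 11 genes were at least 2-fold lower, but its summed reads were only 1.41-fold lower (1.38 to 1.44). Its most abundant genes, psaA and psaB, were 1.51-fold and 1.18-fold lower. Single copies differed, with 1 psbD row at a log2 ratio of -0.59. Movement of reads between copies would leave the sums within 1.5-fold, but the lower bound of the summed ratio was 2.07 for D1 and 1.76 for D2. Such movement stays open for the differences among copies. A response of the summed transcripts to H2O2 may explain the sums, as a hypothesis, and culture-to-culture variation was not measured.

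More genes were lower than higher. With no change built in, 100 Poisson draws at these depths gave an excess of lower over higher genes of at most 64, against 285 observed. Counting noise alone thus gave less than the observed excess. The draws hold no true changes, so they cannot show what the filter of 20 unscaled reads does beside a deeper control. At least 20 control reads were reached by 2642 of the 2673 kept genes. A gene below that in the control could enter only by reaching 20 reads in the shallower library. The ratio of lower to higher genes was at least 1.22 over the scalings tried. Length correction, which recentres each length decile, left 408 higher and 500 lower. The ratio was 0.982 with no minimum count and 0.974 with an unscaled pseudocount of 5, but 3.37 among genes with at least 100 reads. Genes below 0.05 in the DESeq2 column of the authors' deposited table went the other way, with 50 higher and 35 lower, while those below 0.05 in its edgeR column went the same way, with 71 higher of 185. The excess may reflect the treatment, yet its size depends on the scaling. Its presence depends on the read filter and on whether a pseudocount of 5 is scaled to library size. An effect of the filter and a difference between cultures stay open.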
